A study of Mus musculus with 37 samples.

How the data were processed

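The series measured T-cell receptor transcripts by sequencing. Per the labels, iNKT1, iNKT2, iNKT17, CD4T and CD8T cells of the thymus were sorted on a FACSAria III, and libraries were made from total RNA with a SMARTer kit for mouse TCR a/b profiling. BALB/c and B6 mice are inbred strains, given in the labels as genotypes. The deposited files hold 1 clone table per library, with alpha and beta chains together. In each, the authors give a read number per clonotype, in whole counts without normalization or molecular identifiers. The authors also give its fraction of the reads of all chains in the table, which was not used. The assembly tool, its version and its filters are not given in the sources used here, and the processing notes name only genome build mm10. Gene positions come from the annotation of GRCm38.p6, the same build. Positions on chromosome 6 were found for TRBV and TRBJ genes and on chromosome 14 for TRAV genes, 41 of 44 named genes in all.

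Clone tables came in 2 export layouts that differ in their columns. Layout A held 17 libraries and layout B 20, of which 9 and 20 were used. The layout marks a difference in processing, so results are also given within layout B, while layout A alone leaves too few libraries per group for a test. Each table was compared with every other: 4 were the same, byte for byte, under both strain labels, and both copies (8 libraries) were left out because each carries both strain labels. Among the 29 libraries used, the closest of all pairs, within or across groups, had a chi-square per degree of freedom of 12.1 across TRBV genes, so no further pair was a near copy. The labels do not say whether replicates are separate animals, so p-values measure only the spread between samples, which may be technical.

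Reads were assigned to chain, V and J gene by the highest-scoring hit in the table. Clones with a stop codon or frameshift in the CDR3 were left out as non-productive. Productive reads were 92.3% to 96.5% of TRB and 81.9% to 94.9% of TRA reads. Clones whose best V score was tied held 0% to 0.121% of TRB and 0.0680% to 31.8% of TRA reads per library, so TRAV genes were summed over near-identical copies (D and N suffixes). All 37 libraries held 354007 to 1601001 reads (median 501651), 83058 to 527131 productive TRB reads and 194270 to 972850 productive TRA reads. Each TRB clonotype had 1.68 to 41.2 reads on average. Exact binomial (Clopper-Pearson) 95% intervals were computed for the TRAV11-TRAJ18 share of each library, and a floor of 3 reads was used as the lowest share that a library can show.

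Gene usage was tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood on productive reads summed per gene. The library size was all productive reads of the chain, with no scaling factor, because shares of a chain sum to a constant. Genes with a mean share of at least 0.1% in 1 or more groups were tested. The Benjamini-Hochberg method adjusted p over the genes tested in each comparison, with a threshold of 0.05, and all such tests are two-sided. One fit held the 6 iNKT groups (18 TRBV and 12 TRBJ genes), another the 4 CD4T and CD8T groups (22 TRBV and 47 TRAV genes), and the last all 10 groups for iNKT against CD4T, where iNKT is the mean of its 3 subsets. Gene shares are group means with SD, log2 fold changes come from the fit, and their errors are SE. Comparisons were subset against subset and CD8T against CD4T within a strain, strain against strain within a cell type, iNKT against CD4T, and interaction contrasts between strains.

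The genes of each list were fixed before the data were examined, as were tests, thresholds and most alternatives. The iNKT beta list holds TRBV13-2, TRBV13-1, TRBV13-3, TRBV29 and TRBV1. The superantigen list holds TRBV26, TRBV12-1, TRBV12-2, TRBV16 and TRBV15, of which TRBV26 was under the share filter in iNKT cells. Other rearrangements listed were TRAV1-TRAJ33 of mucosal-associated invariant T (MAIT) cells, TRAV13-TRAJ50 of Va10 NKT cells, TRAV genes other than TRAV11 in iNKT cells, TRAV11-TRAJ18 in CD4T and CD8T cells, and TRD and TRG clones. TRAV4 and TRAV9 were listed as alpha families reported as skewed between CD4 and CD8 cells. The text takes the genes it names, in each TRBV comparison, from the iNKT beta genes, the superantigen genes in strain comparisons, and at most 10 genes past the threshold whose libraries do not overlap between groups and whose mean share reaches 1% in a group, by size of change. For TRAV it names the last kind with TRAV4 and TRAV9, and for TRBJ the last kind alone. Genes outside this rule are named as chosen after their values were seen.

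Diversity was the number of productive TRB clonotypes (nucleotide CDR3 with V and J) and the inverse Simpson number after 83058 productive TRB reads were drawn from each library with seed 1. Differences in log2 diversity, in read-weighted CDR3 length and in the TRAV11-TRAJ18 share were tested by exact two-sided permutation of libraries within strain, or within subset for strain comparisons. p-values were adjusted over the 6 comparisons of each measure. Overlap between iNKT libraries was the Morisita-Horn index of amino acid CDR3 with TRBV, tested by exact one-sided permutation of replicate numbers within subsets, or of strain labels within a subset.

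Alternatives were 1 per clonotype in place of reads, TMM scaling, DESeq2 1.42.0, limma 3.58.1 on logit shares with a pseudocount of 0.5 reads, no filter on gene share, clones of at least 10 reads (2256 reads drawn), clones with tied V left out, non-productive clones included, the replicate number as a block, both copies of the shared tables kept or 1 copy under either strain, only the groups compared in the fit, 8305 reads drawn or no equal depth, amino acid in place of nucleotide clonotypes and the reverse for overlap, the Jaccard index of the 1000 most abundant clonotypes, and each library left out in turn. When this left 1 library in a group, that library was assumed to vary like the other groups. Pairing by number was checked as the correlation, across TRBV genes, of each library's deviation from its group mean, with 0.1 as the level that every same-number pair had to exceed. It held for BALB/c iNKT1 with iNKT2 (0.440 to 0.611) and with iNKT17 (0.146 to 0.883), for B6 iNKT1 with iNKT2 (0.367 to 0.486) and for B6 CD4T with CD8T (0.398 to 0.926). It was not met by BALB/c iNKT2 with iNKT17 (lowest 0.0700) or BALB/c CD4T with CD8T (-0.0166), and B6 iNKT17 has 2 numbers in common with each other subset. Groups were therefore tested as unpaired. Other-number pairs reached 0.351 in BALB/c iNKT1 with iNKT17 and 0.791 in B6 CD4T with CD8T. There the check does not single out libraries of the same number. For comparisons of at least 3 libraries per group, the fit was repeated on other splits of the same libraries, all of them or 100 drawn.

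The tests were tested on simulated data, with 50 simulations per comparison, the spread of the real groups and 4 genes changed by 1.5, 2 or 4-fold. For B6 iNKT17 against iNKT2, 63.6% of 4-fold and 12.7% of 2-fold changes were called, and 0.57% of unchanged genes. For the same test in BALB/c, 70% and 16.7% were called. In CD4T cells between strains 100% of 2-fold and 82.8% of 1.5-fold changes were called. For TRBJ in BALB/c iNKT2 against iNKT1, 86.6% of 2-fold changes were called, and for TRAV in B6 95.2%. Permutation tests passed 4.6% of null data sets and 99.7% of those with a 3 SD difference, at a permutation p at or under 0.05. A call in the results needs an adjusted p under 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.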

Results

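Invariant natural killer T (iNKT) cells are innate-like T cells that carry a semi-invariant T-cell receptor. Their TRAV11-TRAJ18 alpha chain pairs with beta chains from a small set of TRBV genes. They mature in the thymus into iNKT1, iNKT2 and iNKT17 cells. The series profiled receptor alpha (TRA) and beta (TRB) transcripts of these 3 subsets and of CD4T and CD8T cells, all sorted from thymuses of 2 strains, BALB/c and B6. Of 37 libraries, 18 carried a BALB/c and 19 a B6 label. Every BALB/c iNKT subset held 4 libraries, and the BALB/c CD4T and CD8T groups held 3 each. Every B6 group held 4 libraries, except iNKT17 with 3. Clone tables of iNKT1 2, iNKT2 2, CD4T 1 and CD8T 1 were the same under both strains, so those 8 libraries were left out. For BALB/c this leaves 3 iNKT1, 3 iNKT2, 4 iNKT17, 2 CD4T and 2 CD8T libraries, and for B6 it leaves 3 per group. The libraries used held 385968 to 1601001 reads (median 506514) and 94652 to 527131 productive TRB reads. Intervals and floors given here cover counting error only, because reads were PCR products without molecular identifiers.

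The invariant alpha chain made up nearly all alpha reads of the iNKT libraries and a trace of those of CD4T and CD8T cells. TRAV11-TRAJ18 took 96.9% ± 1.42 of productive TRA reads in iNKT libraries (SD, n = 19, 93.2 to 99.0). Among BALB/c cells the share was 95.7% ± 2.25 in iNKT1 (n = 3), 97.7% ± 1.55 in iNKT2 (n = 3) and 96.3% ± 0.894 in iNKT17 (n = 4). Among B6 cells it was 98.2% ± 0.313, 97.5% ± 0.821 and 95.9% ± 0.247 in the same order (n = 3 each). CD4T and CD8T libraries held 0.144% ± 0.0395 (n = 10, 0.0839 to 0.200). iNKT libraries exceeded CD4T libraries by 96.7 percentage points, with an exact two-sided permutation p of 6.89e-05 within strain, the smallest that 14520 regroupings can give. The difference from CD8T was also 96.7 points with the same p. Like all tests that pool iNKT subsets, these take libraries of 1 number as independent. In BALB/c such libraries shared clonotypes, so p may be too small. Within layout B, both differences were 96.8 points. Counted once per clonotype instead of by reads, TRAV11-TRAJ18 was 3.03% ± 0.811 of productive TRA clonotypes in iNKT libraries (n = 19) and 0.0672% ± 0.0201 in CD4T and CD8T libraries (n = 10). Alpha chains with a TRAV gene other than TRAV11 held 2.82% ± 1.42 of productive TRA reads in iNKT libraries (n = 19). The lowest alpha share that 3 reads can show was 0.000308% to 0.00154% per library.

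iNKT beta chains used the genes this receptor is known for. Against CD4T cells, TRBV13-2 (the Vb8.2 element, chromosome 6, 41121396 to 41121832) rose in both strains. It held 32.4% ± 3.05 of productive TRB reads in BALB/c iNKT libraries (SD, n = 10) against 7.27% ± 0.138 in CD4T (n = 2). In B6 it held 35.2% ± 7.91 (n = 9) against 8.15% ± 0.129 (n = 3). The log2 fold changes of TRBV13-2 were 2.14 in BALB/c (adjusted p 3.42e-08) and 2.11 in B6 (8.37e-10). TRBV29 (the Vb7 element, 41271403 to 41271881, annotated as a pseudogene segment) held 17.97% ± 8.16 in B6 iNKT against 2.08% ± 0.570 in CD4T (3.00), and 14.9% ± 9.55 against 5.49% ± 0.284 in BALB/c (1.26). The BALB/c TRBV29 call was lost without CD4T library 2 (1.21). TRBV1 (Vb2, 40891296 to 40891885) rose by 1.40 in BALB/c, from 4.36% to 11.6% ± 6.07, and by 0.96 in B6, from 4.69% to 9.17% ± 2.61. TRBV13-1 (Vb8.3, 41116036 to 41116468) rose in B6 (20.9% ± 6.67 against 9.08% ± 0.461, 1.16) and missed the threshold in BALB/c (22.0% ± 8.37 against 14.2% ± 0.265, 0.48, adjusted p 0.0558). It passed there without BALB/c iNKT1 3 (0.51) or iNKT2 1 (0.53). TRBV13-3 (Vb8.1, 41130147 to 41130585) did not pass in either strain (0.41 in BALB/c), although it did in B6 without iNKT2 3 (0.43).

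Other beta genes took smaller shares in iNKT than in CD4T cells, as a rise of some genes requires of shares that sum to a constant. TRBV31 held 3.38% ± 1.53 of BALB/c iNKT reads against 20.8% ± 0.647 in CD4T (-2.67), and 2.11% ± 0.970 against 16.3% ± 1.46 in B6 (-3.07). TRBV5 dropped from 16.4% to 2.02% in BALB/c (-3.06) and TRBV2 from 3.45% to 0.0753% (-5.74). In B6, TRBV2 (-6.50), TRBV26 (-5.35) and TRBV3 (-4.71) fell the most among the named genes. Of 22 TRBV genes tested, 18 passed in BALB/c (3 higher, 15 lower) and 21 in B6 (4 higher, 17 lower). These directions are of shares: TMM and DESeq2 scaling moved the median gene up by 1.57 and 1.13 in BALB/c and by 1.75 and 2.54 in B6. With TMM 7 genes were higher and 8 lower in BALB/c and 6 and 12 in B6, and with DESeq2 6 and 10 in BALB/c and 7 and 8 in B6. Shares of iNKT and CD4T libraries did not overlap for 15 BALB/c and 20 B6 genes, where chance gives 3.03% and 0.909% of genes. Within layout B the counts were 19 and 20, and in BALB/c it was 9 with clones of 10 reads or more. On the iNKT beta list of 5 genes, 3 rose in BALB/c and 4 in B6, and adjusted over the list alone these counts were the same. On the list of genes that endogenous superantigens delete in BALB/c, 4 of 5 fell in BALB/c and all 5 in B6, again unchanged when adjusted over the list alone.

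Beta usage of BALB/c iNKT17 cells differed from that of iNKT2 cells, and less firmly from that of iNKT1 cells. TRBV29 fell from 18.6% ± 6.74 in iNKT1 (n = 3) and 24.4% ± 2.07 in iNKT2 (n = 3) to 5.04% ± 2.54 in iNKT17 (n = 4). TRBV13-1 rose to 31.4% ± 1.81 in iNKT17, from 17.0% ± 2.12 in iNKT1 and 14.6% ± 2.57 in iNKT2. TRBV13-2 took about the same share of each subset, 30.7% ± 2.94, 31.0% ± 2.62 and 34.6% ± 2.52 in iNKT1, iNKT2 and iNKT17, and was not called. TRBV13-3 (7.37%, 8.13% and 6.94%) was not called either. TRBV1 fell from 16.05% ± 8.47 in iNKT1 to 7.26% ± 1.53 in iNKT17, while iNKT2 held 13.0% ± 4.46. For iNKT17 against iNKT2, log2 fold changes were -2.28 ± 0.40 (SE) for TRBV29 (adjusted p 0.000617) and 1.11 ± 0.28 for TRBV13-1 (0.00440). For iNKT17 against iNKT1 they were -1.88 ± 0.40 for TRBV29 (0.00404), 0.89 ± 0.27 for TRBV13-1 (0.0418) and -1.14 ± 0.37 for TRBV1 (0.0418).

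Against iNKT2, BALB/c iNKT17 cells changed in 8 of 18 TRBV genes (7 higher, 1 lower). All 4 tested genes of the superantigen list passed upward, and all 4 also passed adjusted over the list alone: TRBV12-1 (1.43), TRBV12-2 (2.76), TRBV15 (2.94) and TRBV16 (1.62), all 4 named here after their values were seen. The TRBV15 rise rested on iNKT17 3 (3.74%), since the other 3 libraries (0.151% to 0.199%) lay within the iNKT2 range (0.0904% to 0.215%). It was not called without iNKT17 3 (0.31) or any 1 of the iNKT2 libraries (2.70 to 3.39). TRBV12-1 lost its call without iNKT2 1 (1.24) or 4 (1.31) or iNKT17 1 (1.13) or 3 (1.22), and TRBV16 without iNKT2 3 (1.29) or 4 (1.40). TRBV17 rose from 0.351% ± 0.0878 to 0.954% ± 0.167 (1.44), and TRBV19 rose by 1.24 (both named after their values were seen), the latter a call lost without iNKT2 3 (1.04) or 4 (1.14) or iNKT17 4 (0.63). On the iNKT beta list 2 of 5 genes passed with either adjustment. Libraries did not overlap in 5 of 18 genes, where chance gives 5.71%. The count was 8 within layout B, 8 by DESeq2, 5 by limma, 10 with each clonotype counted once and 11 with the replicate number as a block. It was 3 with clones of 10 reads or more and with only the compared groups in the fit, 4 with non-productive clones, 5 with TMM scaling, and 5 without either iNKT2 3 or iNKT2 4. TRBV1 (-0.84, adjusted p 0.0763) passed without iNKT2 1 (-1.10).

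Against iNKT1, BALB/c iNKT17 cells changed in 4 of 18 genes (2 higher, 2 lower). The fourth was TRBV19, at 2.37% ± 1.70 against 0.958% ± 0.171 (1.31, adjusted p 0.0418), whose libraries overlapped and which was picked after its value was seen. It lost its call without any 1 of the iNKT1 libraries (1.18 to 1.43) or iNKT17 1 (1.34) or 4 (0.70). On the iNKT beta list 3 of 5 passed and on the superantigen list none of 4 did, by edgeR with either adjustment. In 3 of 18 genes the libraries did not overlap (chance 5.71%). This count rested on single libraries: it was 1 without iNKT1 1, iNKT1 4, iNKT17 1 or iNKT17 4, and 2 without iNKT1 3. TRBV13-1 lost its call without any of the iNKT1 libraries 1, 3 and 4 or the iNKT17 libraries 1, 3 and 4 (0.80 to 0.98), and TRBV1 without iNKT1 1 or 4 or iNKT17 1, 3 or 4 (-1.27 to -0.63). Within layout B no gene passed by edgeR, with TRBV29 at -1.68 and TRBV13-1 at 1.03. DESeq2 gave 4 genes, limma 2, TMM scaling 2 and each clonotype counted once 7, and clones of 10 reads or more gave 0 (edgeR). Deviations of same-number libraries correlated here too (0.146 to 0.883, other-number pairs -0.71 to 0.351), and with the number as a block 3 genes passed. Of 35 splits of these libraries, 2 gave as many as the real 4.

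BALB/c iNKT2 cells differed from iNKT1 cells in minor genes. TRBV17 (41163092 to 41163556) fell from 1.34% ± 0.426 to 0.351% ± 0.0878 (n = 3 each, -1.94 ± 0.32 SE, adjusted p 0.000252). TRBV12-1 fell from 0.0567% ± 0.0204 to 0.0138% ± 0.0053 (-2.05, 0.0145) and TRBV12-2 from 0.0471% to 0.0121% (-1.99, 0.0292). Both are superantigen list genes named after their values were seen, since their shares lie under 1%. TRBV12-1 lost its call without iNKT1 3 (-1.73) or iNKT2 4 (-1.93), and TRBV12-2 without any 1 of the iNKT1 libraries (-2.01 to -1.98) or iNKT2 1 (-1.61) or 4 (-2.07). None of the 5 iNKT beta genes passed by edgeR, with either adjustment (adjusted p over all genes 0.598 to 0.976). On the superantigen list 2 of 4 fell, and 4 adjusted over the list alone. Of 18 genes, 3 passed, 5 had an unadjusted p under 0.05 and 5 did not overlap (chance 10%). The count was 2 within layout B and 4 by DESeq2 and by limma, but 1 with each clonotype counted once, TMM scaling, clones of 10 reads or more, non-productive clones or only the compared groups in the fit, and 1 without iNKT1 3 or iNKT2 4. Deviations of same-number libraries of these 2 subsets correlated (0.440 to 0.611), and with the number as a block 6 genes passed.

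B6 subsets showed shares that ran the same way for TRBV29 and TRBV13-1, and no gene passed by edgeR with reads as weights and all iNKT groups in the fit. TRBV29 held 19.8% ± 5.47, 24.8% ± 5.51 and 9.33% ± 4.45 in B6 iNKT1, iNKT2 and iNKT17 (n = 3 each). TRBV13-1 held 17.3% ± 1.11, 17.0% ± 6.82 and 28.3% ± 2.47. For iNKT17 against iNKT2, TRBV29 reached -1.41 ± 0.43 (adjusted p 0.0884) and TRBV13-1 0.73 (0.170), and against iNKT1 they reached -1.09 and 0.71 (0.151 each). TRBV13-2 held 38.1% ± 1.18, 36.7% ± 13.9 and 30.9% ± 3.29 in the 3 subsets, TRBV13-3 8.84%, 6.82% and 9.48%, and TRBV1 9.51%, 7.60% and 10.4%. edgeR called 0 of 18 genes for iNKT2 against iNKT1, iNKT17 against iNKT1 and iNKT17 against iNKT2, with 0, 3 and 5 at an unadjusted p under 0.05. DESeq2 called 0, 1 and 2, and limma 0, 0 and 1. Libraries did not overlap in 1, 6 and 10 genes (chance 10%). Layout B alone gave 0 in each (edgeR). With each clonotype counted once 2, 15 and 11 of 18 passed, and with B6 iNKT libraries alone in the fit 0, 5 and 6 of 17 (edgeR). Without B6 iNKT17 3, TRBV29 passed against iNKT2 (-1.80). Adjusted over the list alone, 1 iNKT beta gene passed for iNKT17 against iNKT2, and no superantigen gene in any of these comparisons. The test of whether subset differences themselves differed by strain called TRBV17 for iNKT2 against iNKT1 (-1.57 ± 0.43, adjusted p 0.0417). That count of 1 was 0 by edgeR with each clonotype counted once or with the shared tables kept under both strains, and 15 of 100 splits gave as many. For iNKT17 against iNKT1 and against iNKT2 it called 0 by edgeR, with 3 and 2 genes at an unadjusted p under 0.05, and 4 and 2 with each clonotype counted once. DESeq2 and limma were not run for it, and no list gene passed with either adjustment. With reads as weights, TRBV29 and TRBV13-1 are therefore not shown to differ between strains in these contrasts.

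**Figure D1:**
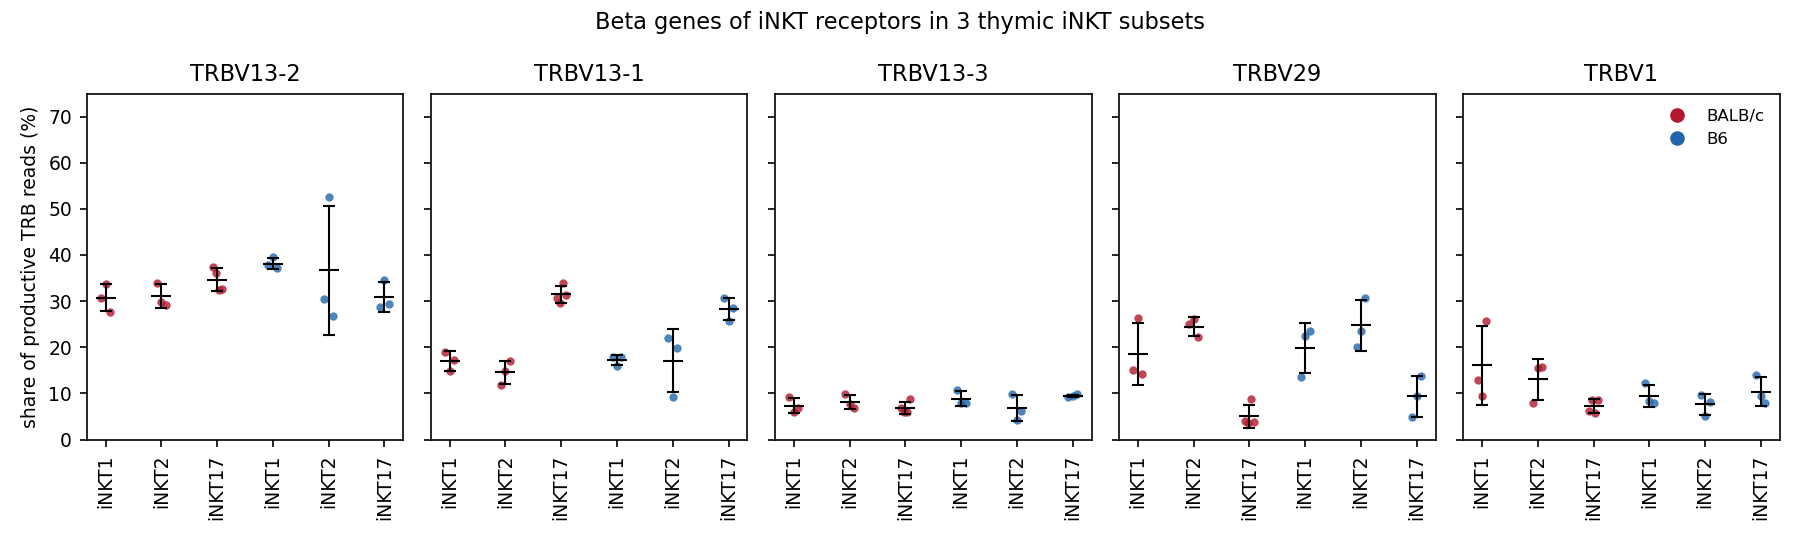
Share of productive TRB reads (%, y axis) of 5 beta genes known from iNKT receptors in BALB/c (red) and B6 (blue) iNKT1, iNKT2 and iNKT17 cells, with 1 point per library and bars at the mean and SD. TRBV13-1 averages 31.4% in BALB/c iNKT17 against 17.0% in iNKT1 and 14.6% in iNKT2, and TRBV29 averages 5.04% against 18.6% and 24.4%.

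Some joining (TRBJ) genes also differed between subsets, most often in BALB/c iNKT17 against iNKT1. In BALB/c, TRBJ1-4 (41534811 to 41534861) stood at 9.14% ± 1.45 in iNKT1, 4.62% ± 0.649 in iNKT2 and 9.24% ± 1.10 in iNKT17. It fell in iNKT2 against iNKT1 (-0.98 ± 0.21 SE, adjusted p 0.00157) and rose in iNKT17 against iNKT2 (1.00, 0.000725). TRBJ1-5 (41535084 to 41535133) rose from 4.65% ± 0.427 in iNKT1 to 8.65% ± 1.04 in iNKT2 (0.89, 0.00339) and 9.95% ± 1.74 in iNKT17 (1.10, 0.000429). TRBJ1-1 rose (0.64) and TRBJ2-5 fell (-0.84) in iNKT17 against iNKT1. TRBJ2-1 fell there too (-0.65), with overlapping libraries and named after its value was seen, and lost its call without iNKT1 1 (-0.60) or 3 (-0.57) or iNKT17 2 (-0.55) or 3 (-0.54). Of 12 genes tested, 2, 4 and 1 passed for iNKT2 against iNKT1, iNKT17 against iNKT1 and iNKT17 against iNKT2, and 2, 1 and 1 within layout B. With clones of 10 reads or more the first and last were 0 by edgeR, and with each clonotype counted once the counts were 4, 9 and 9. Of 10, 35 and 35 splits, 2, 1 and 11 gave as many, with 3, 2 and 3 the highest of the others. The first count was 8 without iNKT2 3. The second was 2 without iNKT17 1, and TRBJ1-1 lost its call without iNKT1 1 or 4 or iNKT17 1 or 4 (0.56 to 0.62), and TRBJ2-5 without iNKT1 3 (-0.71) or iNKT17 1 (-0.72). The third was 4, 3 and 2 without iNKT2 3, iNKT2 4 and iNKT17 4. In B6, TRBJ1-5 rose from 3.61% ± 1.07 in iNKT2 to 6.73% ± 0.722 in iNKT17 (0.90, 0.00662), and TRBJ1-2 fell by 1.10 with overlapping libraries (named after its value was seen). TRBJ1-2 lost its call without iNKT2 3 (-0.14) or any 1 of the iNKT17 libraries (-1.18 to -1.005). That count of 2 was 1 without iNKT2 3 or any 1 of the iNKT17 libraries, and 0 within layout B or with clones of 10 reads or more (edgeR). The other B6 contrasts gave 0 by edgeR, with 1 gene each at an unadjusted p under 0.05. DESeq2 gave 1 for iNKT2 against iNKT1 and 0 for iNKT17 against iNKT1, and limma 0 for both. With each clonotype counted once 7 and 8 of 12 passed in these contrasts and 6 in iNKT17 against iNKT2, and with only the compared groups in the fit 1 and 7 did in the former. Libraries of B6 iNKT2 and iNKT1, iNKT17 and iNKT1, and iNKT17 and iNKT2 did not overlap in 3, 7 and 3 genes (chance 10%). For iNKT2 against iNKT1 the count was 1 without iNKT2 1 or iNKT2 4.

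Strain differences were widest in conventional cells, on the genes known to be deleted in mice with I-E and endogenous mammary tumour virus superantigens, such as BALB/c. In CD8T cells TRBV12-1 (Vb5, 41113567 to 41114067) held 0.181% ± 0.0231 in BALB/c (n = 2) against 8.93% ± 0.398 in B6 (n = 3), a log2 fold change of -5.62 (adjusted p 3.64e-09). In CD4T cells it held 0.186% ± 0.0344 against 2.64% ± 0.135 (-3.83). TRBV12-2 held 0.140% against 4.91% in CD8T (-5.13) and 0.0970% against 1.82% in CD4T (-4.23). TRBV26 (Vb3) fell by 4.67 in CD8T and 3.91 in CD4T, TRBV15 (Vb12) by 3.49 and 3.64, and TRBV16 (Vb11) by 2.33 and 2.79. All 5 list genes were lower in BALB/c in both cell types, over all genes and adjusted over the list alone. TRBV3 was also lower in BALB/c CD4T cells, at 1.01% ± 0.0169 against 5.82% ± 0.318 (-2.53, 1.04e-08). TRBV29 was higher there, at 5.49% against 2.08% (1.40, 0.00192), as were TRBV13-1 (0.64), TRBV5 (0.52), TRBV20 (0.65) and TRBV31 (0.35, named after its value was seen). TRBV20 lost its call without BALB/c CD4T 2 (0.51) or B6 CD4T 3 (0.63) or 4 (0.52), and turned to -0.48 among clones of 10 reads or more. TRBV31 lost its call without either BALB/c CD4T library (0.39 and 0.32) or B6 CD4T 2 (0.30) or 4 (0.34). In CD8T cells TRBV13-2 was higher in BALB/c (10.8% ± 0.1003 against 6.05% ± 0.165, 0.84), as were TRBV13-1 (0.34), TRBV13-3 (0.43), TRBV5 (0.71), TRBV31 (0.54) and TRBV2 (0.52). TRBV2 lost its call without BALB/c CD8T 2 (0.58) or 3 (0.46) or B6 CD8T 3 (0.45) or 4 (0.40), and turned to -0.39 among clones of 10 reads or more. In CD4T cells TRBV13-2 was lower in BALB/c (-0.16, adjusted p 0.0346), but higher with TMM (0.020) or DESeq2 (0.14) scaling, and it lost its call without any 1 of the 5 libraries (-0.18 to -0.15).

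Of 22 TRBV genes, 13 passed in CD4T (5 higher in BALB/c, 8 lower) and 14 in CD8T (8 higher, 6 lower). Libraries did not overlap in 17 and 15 genes (chance 20%). The counts were 16 and 17 within layout B, and in CD8T it was 5 with clones of 10 reads or more. On the iNKT beta list 3 of 5 passed in each cell type, and 4 in CD4T and 3 in CD8T adjusted over the list alone. Each of these comparisons leaves 2 BALB/c libraries, and with the tables found under both strains kept under both labels no gene passed by edgeR in either cell type.

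**Figure D2:**
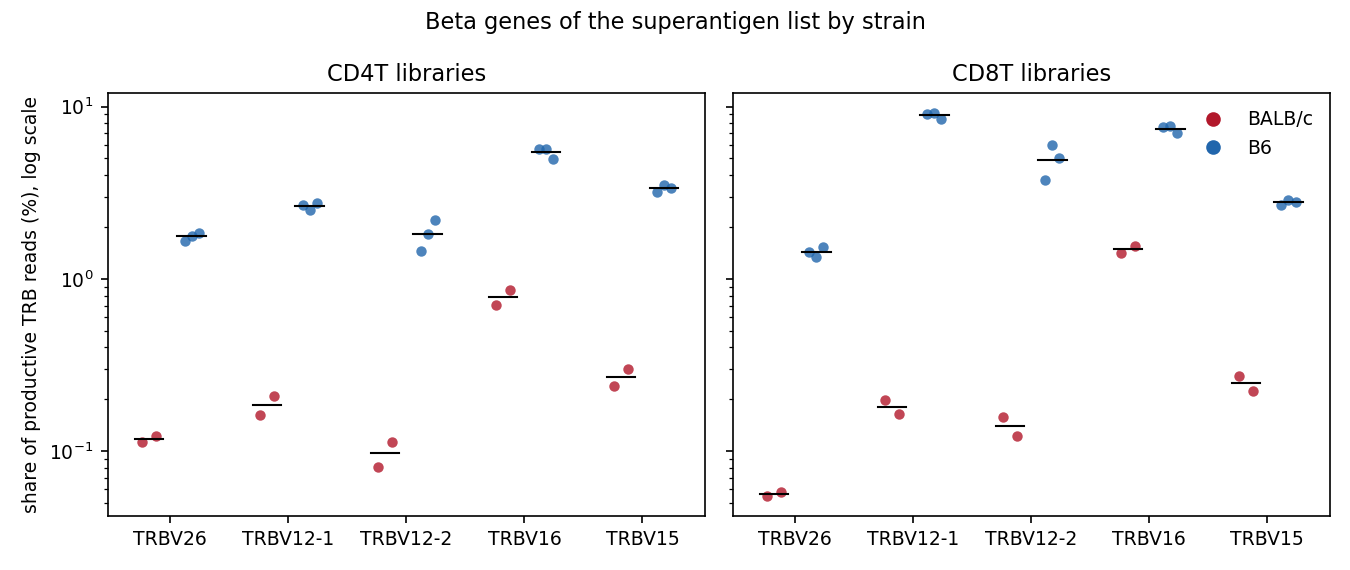
Share of productive TRB reads (%, log scale on the y axis) of 5 beta genes deleted by endogenous superantigens, in CD4T (left) and CD8T (right) libraries of BALB/c (red) and B6 (blue), with 1 point per library and lines at the mean. TRBV12-1 averages 0.181% in BALB/c CD8T cells and 8.93% in B6.

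In iNKT cells strain differences were few with reads as weights. BALB/c iNKT17 cells used TRBV19 more (2.37% ± 1.70, n = 4, against 0.591% ± 0.177, n = 3, log2 2.00 ± 0.46 SE, adjusted p 0.00396) and TRBV12-1 less (0.0365% against 0.228% ± 0.0858, -2.63, 0.000893). BALB/c iNKT2 cells used less TRBV12-1 (0.0138% against 0.103%, -2.91), TRBV12-2 (0.0121% against 0.0881%, -2.90) and TRBV17 (0.351% against 0.703% ± 0.198, -1.004, adjusted p 0.0296, named after its value was seen). The counts of 3 in iNKT2 and 2 in iNKT17 were 2 and 2 within layout B. TRBV17 lost its call without BALB/c iNKT2 1 (-0.89) or 3 (-0.92) or B6 iNKT2 1 (-0.96) or 4 (-0.81). In iNKT1 cells edgeR, DESeq2 and limma each called 0 of 18 genes, with 2 at an unadjusted p under 0.05 (edgeR). With each clonotype counted once 7, 5 and 12 of 18 genes passed in iNKT1, iNKT2 and iNKT17. The iNKT17 count was 0 by edgeR with clones of 10 reads or more or with only the compared groups in the fit, and 4 of 35 splits gave as many. The iNKT2 count was 0 by edgeR with the shared tables kept under both strains. On the superantigen list 0, 2 and 1 of 4 genes passed in iNKT1, iNKT2 and iNKT17, and as many adjusted over the list alone. No iNKT beta gene passed by edgeR in any subset with either adjustment. In iNKT17, TRBV29 (-0.89, adjusted p 0.231) passed without BALB/c iNKT17 3 (-1.31) and TRBV12-2 without BALB/c iNKT17 4 (-1.39). In iNKT2, TRBV16 (-0.77) passed without BALB/c iNKT2 1 (-1.57). Libraries did not overlap in 5, 5 and 3 genes of iNKT1, iNKT2 and iNKT17 (chance 10%, 10% and 5.71%).

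CD8T and CD4T cells differed in both chains. Among alpha genes TRAV16 rose in CD8T, to 11.8% ± 0.0499 from 4.74% ± 0.511 in BALB/c (n = 2 each, log2 1.32, adjusted p 0.000132) and to 10.7% ± 0.977 from 3.798% ± 0.410 in B6 (n = 3 each, 1.49, 1.35e-05). TRAV4 (Va11) is a family reported as skewed to CD4 cells. TRAV4-4 fell in CD8T from 3.19% to 1.09% in BALB/c (-1.55) and from 4.76% to 1.76% in B6 (-1.43), and TRAV4-2 fell by 1.97 and 1.53. TRAV4-3 passed in neither strain. In the TRAV9 (Va3) family, reported as skewed to CD8 cells, TRAV9-1 fell in both strains (-0.62 and -1.42), TRAV9-3 rose in B6 (1.29), and TRAV9-2 and TRAV9-4 passed in neither. The BALB/c TRAV9-1 call was lost without any 1 of the 4 libraries (-0.73 to -0.50). In BALB/c, TRAV2 (2.18) and TRAV6-1 (1.45) rose, and TRAV14-3 (-1.72), TRAV14-2 (-1.25), TRAV19 (-1.05), TRAV21 (-1.03) and TRAV17 (-0.94) fell. TRAV21 lost its call without BALB/c CD8T 2 (-0.91). TRAV19 rose in B6 (0.71, adjusted p 0.00400, named after its value was seen). In B6, TRAV12-3 (1.01), TRAV12-2 (0.92), TRAV12-1 (0.86) and TRAV3-3 (0.79) rose, and TRAV7-4 (-0.94), TRAV7-2 (-0.91) and TRAV14-3 (-0.80) fell. TRAV7-4 lost its call without B6 CD8T 3 (-0.83) or 4 (-0.78). Of 47 TRAV genes, 18 passed in BALB/c (9 each way) and 25 in B6 (13 higher, 12 lower), and 33 in each strain within layout B. With the replicate number as a block 32 and 38 passed, where same-number deviations correlated in B6 (0.398 to 0.926, other-number pairs -0.914 to 0.791) but not in BALB/c (-0.0166). With clones of 10 reads or more 7 and 14 passed. In 39 BALB/c and 25 B6 genes the libraries did not overlap (chance 33.3% and 10%).

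Among beta genes, TRBV31 fell in CD8T from 20.8% ± 0.647 to 6.71% ± 0.162 in BALB/c (-1.64) and from 16.3% ± 1.46 to 4.62% ± 0.559 in B6 (-1.82). TRBV14 (1.60 and 1.75) and TRBV17 (1.68 and 1.56) rose in both strains. TRBV13-2 rose in BALB/c (0.57) and fell in B6 (-0.43), TRBV13-3 rose in both (0.97 and 0.32), and TRBV13-1 passed in B6 alone (0.41). TRBV3 rose in BALB/c (3.78% against 1.01%, 1.91) and fell in B6 (-0.67). TRBV12-1 (1.76), TRBV12-2 (1.43) and TRBV29 (7.06% ± 1.97 against 2.08%, 1.76) rose in B6, where TRBV2 fell (-1.49). TRBV29 also passed in BALB/c (0.83), but lost its call without any 1 of the 4 libraries (0.78 to 0.88), and BALB/c TRBV2 lost it without CD8T 2 (-0.78). In B6, TRBV20 lost its call without CD8T 3 or 4 (-0.53 and -0.54), and TRBV1 (-0.27) without CD4T 3, CD8T 3 or CD8T 4 (-0.24 to -0.22). Among clones of 10 reads or more B6 TRBV1 turned to 0.50. The counts were 13 of 22 in BALB/c (8 higher, 5 lower) and 18 in B6 (8 higher, 10 lower), and 14 and 19 within layout B, but 4 and 6 with clones of 10 reads or more. On the iNKT beta list 3 passed in BALB/c and 5 in B6, and on the superantigen list 2 and 5, with the same counts adjusted over the list alone. Libraries did not overlap in 17 BALB/c and 18 B6 genes (chance 33.3% and 10%). A test of whether the CD8T minus CD4T difference itself differed by strain, chosen after the data were seen, called 5 of 22 genes, with 11 at an unadjusted p under 0.05: TRBV3 (2.58, adjusted p 1.44e-07), TRBV12-1 (-1.79), TRBV13-2 (1.00), TRBV26 (-0.77) and TRBV13-3 (0.65). The count was 8 with each clonotype counted once, 12 with layout as a term and 0 by edgeR with the shared tables kept under both strains. Of the 5 genes, 2 are on the iNKT beta list and 2 on the superantigen list, with 3 of each adjusted over the list alone.

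Averaged over subsets, iNKT repertoires held fewer beta clonotypes than CD4T repertoires, although B6 iNKT1 did not, and iNKT17 held the fewest. With 83058 reads drawn from each library, BALB/c iNKT1, iNKT2 and iNKT17 held 21661 ± 7168, 12743 ± 2318 and 8707 ± 1311 productive clonotypes (SD, n = 3, 3 and 4). B6 subsets held 48469 ± 9448, 22099 ± 2120 and 6059 ± 2438 (n = 3 each). CD4T libraries held 46472 ± 5252 in BALB/c (n = 2) and 46622 ± 6012 in B6 (n = 3), and CD8T libraries 40825 ± 9429 and 40935 ± 2478. iNKT2 held 0.529 times the clonotypes of iNKT1 (exact two-sided permutation p 0.01, adjusted 0.015), iNKT17 0.223 times those of iNKT1 and 0.422 times those of iNKT2 (0.00143 each, the smallest possible, adjusted 0.00429). iNKT cells held 0.327 times those of CD4T (exact p 0.00241, adjusted 0.00482), with libraries of 1 number as independent. CD8T against CD4T (0.876) had an exact p of 0.183. BALB/c against B6 within iNKT subsets (0.720, exact p 0.0819) missed the threshold, and passed without B6 iNKT17 1. Within layout B the log2 differences among subsets were -1.15, -2.17 and -1.02, with adjusted exact p 0.0833 each. At 8305 reads per library they were -0.67, -1.09 and -0.42, the last without a call. Among clones of 10 reads or more, with 2256 reads drawn, they turned to 0.72, 1.21 and 0.49 without a call, so the order of the subsets depends on this setting, where filter and depth change together. Equal reads do not equalize the number of cells behind each library. Productive TRB reads per clonotype were 1.68 to 2.34 in B6 iNKT1 and 19.5 to 41.2 in B6 iNKT17. Whether cell input sets the order of the subsets was not tested.

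Evenness differed more by strain than did clonotype number. The inverse Simpson number, which falls when a few clones dominate, was 357 ± 344, 109 ± 24.5 and 238 ± 69.4 in BALB/c iNKT1, iNKT2 and iNKT17. In B6 it was 27428 ± 5021, 4183 ± 5923 and 1205 ± 697. BALB/c iNKT libraries stood at 0.0718 times B6 (exact two-sided permutation p 0.00871, adjusted 0.0261), a call lost without B6 iNKT2 1 (log2 -3.55) or 4 (-3.08), and -4.17 within layout B without a call. iNKT stood at 0.0212 times CD4T (exact p 0.000275, adjusted 0.00165) and at log2 -5.75 within layout B. iNKT2 against iNKT1 (0.0973, exact p 0.025, adjusted 0.05) and iNKT17 against iNKT1 (0.194, exact p 0.05, adjusted 0.075) did not pass. Both passed without BALB/c iNKT1 4, and the former also without B6 iNKT2 1 or 4. iNKT17 against iNKT2 (2.00, exact p 0.64) did not pass either, and turned to log2 -0.45 without B6 iNKT2 3. In that library 1 clone held 31.9% of productive TRB reads.

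**Figure D3:**
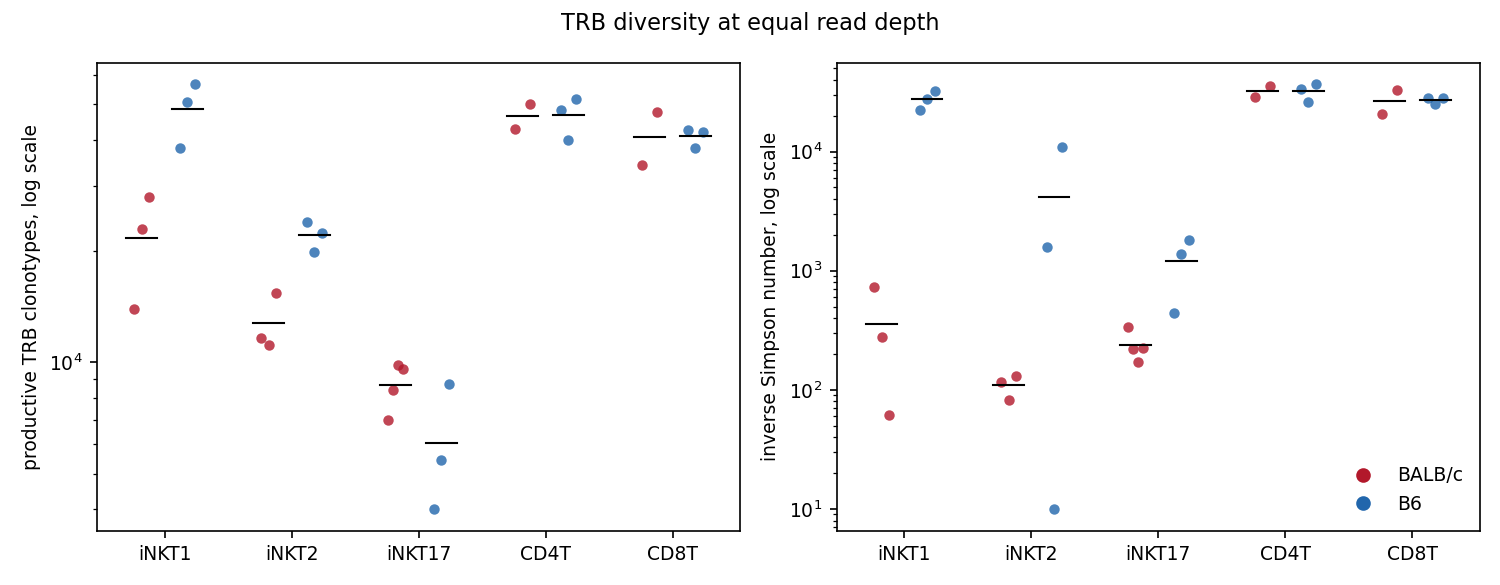
Productive TRB clonotypes (left) and inverse Simpson number (right), both on log scales, after drawing 83058 reads from each library, for 5 cell types of BALB/c (red) and B6 (blue), with 1 point per library and lines at the mean. B6 clonotypes average 48469 in iNKT1 and 6059 in iNKT17.

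BALB/c iNKT2 beta chains had shorter CDR3 loops, the part of the chain that V, D and J joining forms, while in B6 this rested on 1 library. The read-weighted mean length was 14.0 ± 0.194, 13.4 ± 0.170 and 14.1 ± 0.170 amino acids in BALB/c iNKT1, iNKT2 and iNKT17. In B6 it was 14.1 ± 0.0319, 13.7 ± 0.552 and 14.1 ± 0.101, with iNKT2 libraries at 13.96 (iNKT2 1), 13.05 (iNKT2 3) and 14.05 (iNKT2 4). Over both strains, iNKT2 differed from iNKT1 by -0.484 (exact two-sided permutation p 0.005, adjusted 0.015) and iNKT17 from iNKT2 by 0.540 (exact p 0.00143, adjusted 0.00857). Within TRBV13-2 alone the differences were -0.700 and 0.742 with the same p-values. The first lost its call without any 1 of the B6 iNKT1 libraries (-0.492 to -0.476 over all TRBV, -0.709 to -0.691 within TRBV13-2). The second lost it without B6 iNKT17 1 (0.511), and within TRBV13-2 without any 1 of the B6 iNKT17 libraries (0.712 to 0.766). Without B6 iNKT2 3 they were -0.326 and 0.381, and within TRBV13-2 -0.376 and 0.418. Within layout B they were -0.482 and 0.502 without a call. The other length comparisons did not pass: iNKT17 against iNKT1 0.0557, CD8T against CD4T -0.0113, iNKT against CD4T 0.0691, and BALB/c against B6 -0.153 (adjusted exact p 0.425 to 0.690), the last of which passed without B6 iNKT2 3 (-0.259).

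Clonotypes were shared across BALB/c iNKT subsets mainly between libraries of the same number. The Morisita-Horn index of amino acid clonotypes averaged 0.134 (0.0225 to 0.349, 9 pairs) between subsets at the same number, against 0.00379 (24 pairs) at other numbers. An exact one-sided permutation p of 0.00694 was the smallest that 144 regroupings allow. In layout B the difference was 0.152, with an exact one-sided p of 0.25. In B6 the means were 0.0480 (7 pairs) and 0.0309 (20 pairs), with an exact one-sided p of 0.222 over 36 regroupings. Within a subset, libraries of 1 strain overlapped more (0.0464) than libraries of different strains (0.00493), a difference of 0.0480 averaged over subsets (exact one-sided permutation p 0.00143). The 3 pairs of B6 iNKT1 libraries (mean 0.267) carry most of this, as the other 18 pairs within groups averaged 0.00965 (0.000596 to 0.0280). Within layout B it was 0.0600 (exact one-sided p 0.0370).

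**Figure D4:**
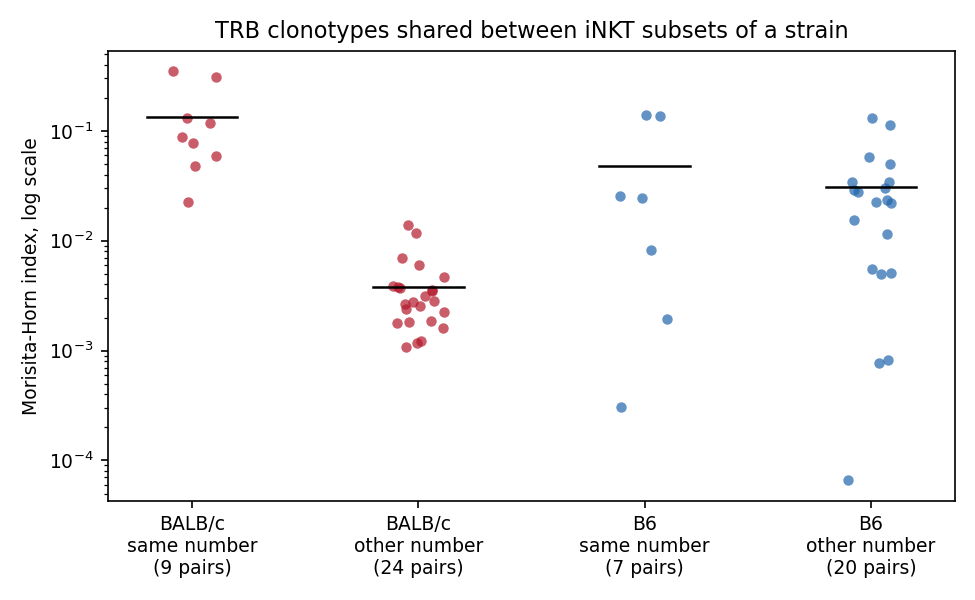
Morisita-Horn index of TRB clonotypes (log scale on the y axis) for pairs of libraries from different iNKT subsets of BALB/c (red) and B6 (blue), by whether they carry the same replicate number, with lines at the mean. BALB/c pairs of the same number average 0.134 and those of other numbers 0.00379.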

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

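Tests on the clone tables found under both strains, on carry-over in both directions, on the large clone and on spread shared between strains, and the interaction of CD8T minus CD4T with strain, were chosen only after the result was seen. A library stood out when, among 4 libraries of a group, the gap to its nearest neighbour took more of the range than Dixon's test allows at 0.05. Shares of 28 beta gene values were tested this way and 3 stood out, while chance gives about 1 in 20. In BALB/c iNKT17 3, TRBV15 held 3.74% of productive TRB reads against 0.151% to 0.199% in the other 3 libraries. The same library held 8.85% TRBV29 against 3.57% to 3.91%. In BALB/c iNKT17 1, TRBV4 held 3.896% against 0.525% to 0.796%.

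Differences between groups were singled out where the test of the difference itself passed its threshold. For iNKT2 against iNKT1 this was TRBV17, whose log2 change in BALB/c minus that in B6 was -1.57. For CD8T against CD4T they were TRBV3 (2.58), TRBV12-1 (-1.79), TRBV13-2 (1.00), TRBV26 (-0.77) and TRBV13-3 (0.65). Some reads took no part in the comparisons. Reads that join a TRDV to a TRAJ gene reached 3202 in 1 library, with 22 to 180 in the 12 iNKT and 1371 to 3202 in the 8 CD4T and CD8T libraries of layout B and 0 in the 17 of layout A. Reads of TRD and TRG chains reached 96 in a library.

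The first pattern weighed is that 4 clone tables were the same under both strains, 1 each of iNKT1, iNKT2, CD4T and CD8T. For the CD4T and CD8T tables a BALB/c origin is argued against, because superantigen list genes held 15.7% and 24.8% of their beta reads, at least 10.8 times the BALB/c means (1.46% ± 0.219 and 2.11% ± 0.0309), and the B6 means (15.0% ± 0.368 and 25.5% ± 1.39) lay within 1.77 SD. For iNKT1 a BALB/c origin is argued against too, since the table overlapped with each B6 iNKT1 library at 0.203 or more and with BALB/c iNKT1 libraries at 0.0129 or less. For iNKT2 overlap runs the other way, with 0.00187 to 0.00266 for BALB/c and 0.000195 to 0.00117 for B6 iNKT2 libraries, although pairs of BALB/c iNKT2 libraries overlap more (0.0081 to 0.0280), but within layout A, the layout of the table, a BALB/c origin is argued against: 99.96% of its invariant reads listed TRAV11 ahead of TRAV11N (BALB/c 0.00142% to 0.00677%, n = 4, B6 99.7% to 99.9%, n = 3), and the mean score of TRAV11 minus that of TRAV11N was 19.7 (BALB/c -40.6 to -27.8, B6 3.79 to 24.3). In iNKT libraries of layout B both strains list TRAV11 ahead in at least 99.99% of reads, with scores still apart (BALB/c 39.2 to 41.8, B6 68.5 to 71.4). The hit order of the iNKT2 table can therefore be read only within layout A. The shared iNKT2 table also overlapped with the shared iNKT1 table at 0.0585, against 0.000759 to 0.00118 with the other iNKT1 libraries of both strains. This goes with 1 strain for both tables, although what their shared number marks is not given. That all 4 are B6 tables also stored under BALB/c names is a candidate explanation that stays open, with no biological explanation tested.

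The next is that BALB/c iNKT libraries of the same number shared expanded clonotypes across subsets. Carry-over in 1 direction and a fixed proportion stays open. Ratios of clone frequency spanned a median 146-fold (10th to 90th percentile, under 10-fold needed), but 7.2-fold in other-number pairs of the same layout. These share few clonotypes, so the range cannot decide. Carry-over in both directions in fixed proportions is argued against, since a median of 17.5 of the 100 largest clonotypes lay within 10-fold in the other library. Sharing among all libraries of a layout is argued against by the mean overlap of other-number pairs of the same layout, 0.00457, below the lowest same-number pair (0.0225). That libraries of the same number come from the same animal or pool stays an open hypothesis, untested as the labels do not say what the numbers mark.

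The last is that edgeR called 0 TRBV genes between B6 iNKT subsets with reads as weights, with 0, 3 and 5 at an unadjusted p under 0.05 for iNKT2 against iNKT1, iNKT17 against iNKT1 and iNKT17 against iNKT2, while DESeq2 called 0, 1 and 2 and limma 0, 0 and 1. The large clone of B6 iNKT2 3 stays open as part of the cause, since with its reads removed edgeR called 2 genes for iNKT17 against iNKT1 and 1 for iNKT17 against iNKT2. Spread that the fit shares with BALB/c libraries remains a candidate explanation, since a fit of B6 iNKT libraries alone called 0, 5 and 6 of 17 genes, so that the lower count of the comparisons with iNKT17 was 5. Differences in clone size between libraries remain another, since the SD between libraries with each clonotype counted once was a median 0.837 times that with reads. Whether B6 subsets differ less than BALB/c subsets in biology was tested only by the interaction contrasts, which called TRBV17 alone with reads as weights and 0, 4 and 2 genes (edgeR) with each clonotype counted once.

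The model was also fitted to other splits of the same libraries. For TRBV, 35 splits of BALB/c iNKT17 with iNKT2 gave as many genes as the real one (8) once, the real split itself, with 5 as the next highest. That is the lowest share 35 splits allow, and shares were not adjusted over the comparisons. Chance is therefore argued against for this count alone. For iNKT17 against iNKT1 in BALB/c chance is not excluded, as 2 of 35 splits gave 4 genes or more (real 4, highest other 4; 3 genes with the replicate number as a block). Nor is it for iNKT17 between strains (4 of 35, real 2, highest other 4). For B6 iNKT against CD4T, 1 of 100 splits (real 21, highest other 17) argues against chance for this count alone. For the interactions of strain with iNKT2 against iNKT1, iNKT17 against iNKT1 and iNKT17 against iNKT2, 15, 100 and 100 of 100 splits gave as many as the real 1, 0 and 0 (highest other 2, 2 and 4; edgeR), and chance is not excluded. For BALB/c TRBJ, 1 of 35 (real 4, highest other 2) argues against chance for the iNKT17 against iNKT1 count alone. For iNKT17 against iNKT2, chance is not excluded (11 of 35, real 1, highest other 3).

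With 10 splits a share under 0.05 cannot be reached. TRBV counts of this kind were 3 for BALB/c iNKT2 against iNKT1 (1 of 10, highest other 0), 3 for iNKT2 between strains (1 of 10, highest other 0) and 18 for B6 CD8T against CD4T (1 of 10, highest other 0). They were 0 by edgeR, with highest other 0, for iNKT1 between strains and all B6 comparisons of iNKT subsets (10 of 10 each). TRBJ counts were 2 for BALB/c iNKT2 against iNKT1 (2 of 10, highest other 3), 2 for B6 iNKT17 against iNKT2 (1 of 10, highest other 1) and 0 by edgeR for the other B6 comparisons (10 of 10 each, highest other 0). The TRAV count of B6 CD8T against CD4T was 25 (1 of 10, highest other 0).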

How the results depend on the processing

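Restriction to layout B, layout as a term of the fit, settings other than clonotype weight and TMM for TRBJ and every setting but libraries left out for TRAV, single copies of the shared tables for diversity and length, and the renumbering of B6 iNKT17 were chosen after the data were seen. The invariant alpha share kept its direction and its call in every setting run (2.99 to 96.9 points over CD4T, the lowest with each clonotype counted once). Of edgeR, DESeq2 and limma counts of genes past the threshold, 251 stayed within 1.5 times their value and 100 did not, and with libraries left out in turn 128 did and 21 did not. Of log2 fold changes of named genes, 2287 kept direction and call, 60 gained a call, 206 lost one and 95 changed sign, and with libraries left out 1073, 8, 47 and 32 did. Diversity, length and overlap kept both in 141 cases, gained a call in 12, lost it in 14 and changed sign in 13 (445, 7, 12 and 5 with libraries left out). Genes that had passed and changed sign were TRBV13-2 and TRBV20 in CD4T between strains, TRBV2 in CD8T between strains and TRBV1 in B6 CD8T against CD4T. The superantigen genes of CD4T and CD8T cells kept their direction between strains in every setting run. With the replicate block, which pairs libraries by number, counts were 6 for TRBV in BALB/c iNKT2 against iNKT1 and 32 and 38 for TRAV in CD8T against CD4T of BALB/c and B6. TMM and DESeq2 change the scale from shares to ratios against a typical gene, and moved the median TRBV gene of iNKT against CD4T by 1.13 to 2.54, of iNKT subsets within a strain by -0.64 to 0.50 and of the other comparisons by -0.085 to 0.35. Keeping a shared table under both strains puts the same reads on both sides of a strain comparison, and fits of 2 groups have fewer libraries to estimate spread. The 10-read filter leaves some gene totals near 0 reads, as for TRBV12-1 and TRBV12-2 in iNKT1. Within layout B, BALB/c iNKT1 and iNKT2 and B6 groups keep too few libraries for several permutation tests to pass. Counts of 0 listed here are by edgeR. For all other changes listed here the cause was not tested. Depth limits alpha shares to 0.000308% to 0.00154% per library.

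With each clonotype counted once, TRBV counts were 0 for the strain difference in iNKT2 against iNKT1, 1 for BALB/c iNKT2 against iNKT1, 2 for B6 iNKT2 against iNKT1 and the strain difference in iNKT17 against iNKT2, 4 for the strain difference in iNKT17 against iNKT1, 5 for iNKT2 between strains, 7 for BALB/c iNKT17 against iNKT1 and iNKT1 between strains, 8 for the strain difference in CD8T against CD4T, 11 for B6 iNKT17 against iNKT2, 12 for iNKT17 between strains and 15 for B6 iNKT17 against iNKT1. TRBJ counts were 4 for BALB/c iNKT2 against iNKT1, 6 for B6 iNKT17 against iNKT2, 7 for B6 iNKT2 against iNKT1, 8 for B6 iNKT17 against iNKT1 and 9 for BALB/c iNKT17 against iNKT1 and BALB/c iNKT17 against iNKT2. The sign turned for TRBV13-2 (-0.27 in BALB/c iNKT2 against iNKT1, -0.19 in BALB/c iNKT17 against iNKT1, 0.085 in B6 iNKT17 against iNKT1, 0.21 in B6 iNKT17 against iNKT2, 0.012 in iNKT1 between strains, -0.26 in iNKT17 between strains), TRBV13-1 (0.063 in BALB/c iNKT2 against iNKT1, 0.018 in iNKT2 between strains), TRBV13-3 (-0.082 in BALB/c iNKT2 against iNKT1, 0.30 in BALB/c iNKT17 against iNKT1, 0.39 in BALB/c iNKT17 against iNKT2, -0.077 in B6 iNKT17 against iNKT1, -0.019 in iNKT2 between strains, 0.29 in iNKT17 between strains), TRBV1 (0.23 in BALB/c iNKT17 against iNKT2, 0.17 in iNKT17 between strains, 0.047 in CD4T between strains), TRBV15 (-0.37 in iNKT1 between strains, -0.76 in iNKT17 between strains), TRBV29 (0.14 in iNKT2 between strains), TRAV9-4 (0.094 in BALB/c CD8T against CD4T), TRAV4-3 (0.013 in B6 CD8T against CD4T). A change of sign was seen for differences in CDR3 length (0.0229 in CD8T against CD4T, 0.0738 in BALB/c against B6) and CDR3 length within TRBV13-2 (0.0668 in BALB/c against B6). Calls were gained for CDR3 length (0.129 in iNKT17 against iNKT1, 0.345 in iNKT against CD4T) and CDR3 length within TRBV13-2 (0.183 in iNKT17 against iNKT1, 0.472 in iNKT against CD4T). With TMM scaling, TRBV counts were 1 for BALB/c iNKT2 against iNKT1 and B6 iNKT17 against iNKT2, 2 for BALB/c iNKT17 against iNKT1 and 5 for BALB/c iNKT17 against iNKT2. Signs were the opposite for TRBV13-1 (0.25 in BALB/c iNKT2 against iNKT1, 0.15 in B6 iNKT2 against iNKT1, 0.082 in iNKT2 between strains), TRBV1 (0.18 in BALB/c iNKT2 against iNKT1, -0.018 in B6 iNKT17 against iNKT1, 0.082 in CD4T between strains), TRBV13-2 (-0.034 in BALB/c iNKT17 against iNKT1, -0.47 in BALB/c iNKT17 against iNKT2, 0.41 in B6 iNKT2 against iNKT1, 0.020 in CD4T between strains), TRBV13-3 (-0.085 in B6 iNKT17 against iNKT1), TRBV29 (0.081 in iNKT2 between strains), TRAV9-4 (0.11 in BALB/c CD8T against CD4T).

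By DESeq2, TRBV counts were 1 for B6 iNKT17 against iNKT1, 2 for B6 iNKT17 against iNKT2 and 5 for iNKT2 between strains. TRBJ counts were 1 for B6 iNKT2 against iNKT1 and 4 for BALB/c iNKT17 against iNKT2. In the other direction were TRBV13-1 (0.34 in BALB/c iNKT2 against iNKT1, 0.18 in B6 iNKT2 against iNKT1, 0.10 in iNKT2 between strains), TRBV1 (0.25 in BALB/c iNKT2 against iNKT1, -0.20 in B6 iNKT17 against iNKT1, -0.14 in B6 iNKT17 against iNKT2, 0.20 in CD4T between strains), TRBV13-2 (-0.33 in BALB/c iNKT17 against iNKT2, 0.36 in B6 iNKT2 against iNKT1, 0.14 in CD4T between strains), TRBV13-3 (-0.25 in B6 iNKT17 against iNKT1, -0.11 in B6 iNKT17 against iNKT2, 0.089 in CD4T between strains), TRBV29 (0.15 in iNKT2 between strains), TRBV16 (0.15 in iNKT17 between strains). By limma, TRBV counts were 1 for B6 iNKT17 against iNKT2, 2 for BALB/c iNKT17 against iNKT1 and 5 for BALB/c iNKT17 against iNKT2. The TRBJ count was 1 for B6 iNKT17 against iNKT2. Log2 fold changes of the other sign were found for TRBV15 (-0.26 in iNKT17 between strains).

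With clones of 10 reads or more alone, TRBV counts were 0 for BALB/c iNKT17 against iNKT1 and iNKT17 between strains, 1 for BALB/c iNKT2 against iNKT1, B6 iNKT17 against iNKT1, iNKT1 between strains and iNKT2 between strains, 3 for BALB/c iNKT17 against iNKT2, 4 for BALB/c CD8T against CD4T, 5 for CD8T between strains, 6 for B6 CD8T against CD4T and 9 for BALB/c iNKT against CD4T. TRBJ counts were 0 for BALB/c iNKT2 against iNKT1, BALB/c iNKT17 against iNKT2 and B6 iNKT17 against iNKT2. TRAV counts were 7 for BALB/c CD8T against CD4T and 14 for B6 CD8T against CD4T. The sign turned for TRBV13-3 (0.15 in BALB/c iNKT17 against iNKT1, -0.61 in B6 iNKT17 against iNKT1), TRBV13-2 (0.11 in B6 iNKT2 against iNKT1), TRBV1 (-0.41 in B6 iNKT17 against iNKT1, -1.02 in CD8T between strains, 0.50 in B6 CD8T against CD4T), TRBV29 (0.57 in iNKT1 between strains), TRBV12-1 (8.36 in iNKT1 between strains), TRBV12-2 (8.85 in iNKT1 between strains), TRBV16 (0.48 in iNKT1 between strains), TRBV20 (-0.48 in CD4T between strains), TRBV2 (-0.39 in CD8T between strains), TRBV13-1 (-0.23 in BALB/c iNKT against CD4T, -0.026 in BALB/c CD8T against CD4T), TRAV4-3 (0.0083 in B6 CD8T against CD4T), TRAV9-2 (0.98 in B6 CD8T against CD4T). A change of sign was seen for differences in log2 clonotype number (0.72 in iNKT2 against iNKT1, 1.21 in iNKT17 against iNKT1, 0.49 in iNKT17 against iNKT2, 0.40 in CD8T against CD4T) and log2 inverse Simpson number (1.82 in iNKT17 against iNKT1, 0.45 in CD8T against CD4T). Calls were lost for log2 clonotype number (-0.32 in iNKT against CD4T) and log2 inverse Simpson number (-1.30 in BALB/c against B6, -2.52 in iNKT against CD4T). With non-productive clones included, TRBV counts were 1 for BALB/c iNKT2 against iNKT1, iNKT2 between strains and iNKT17 between strains, 2 for BALB/c iNKT17 against iNKT1 and 4 for BALB/c iNKT17 against iNKT2. Signs were the opposite for TRBV13-2 (-0.017 in BALB/c iNKT2 against iNKT1), TRBV16 (0.33 in iNKT2 between strains, 0.13 in iNKT17 between strains), TRBV15 (0.058 in iNKT2 between strains), TRAV9-4 (0.0090 in BALB/c CD8T against CD4T), TRAV9-2 (0.0012 in B6 CD8T against CD4T). Without clones of tied V, in the other direction were TRAV4-3 (0.019 in B6 CD8T against CD4T). Without a filter on gene share, TRBV counts were 1 for BALB/c iNKT17 against iNKT1 and 4 for iNKT17 between strains. With only the groups compared in the fit, TRBV counts were 0 for iNKT17 between strains, 1 for BALB/c iNKT2 against iNKT1 and iNKT2 between strains, 2 for BALB/c iNKT17 against iNKT1, 3 for BALB/c iNKT17 against iNKT2, 4 for B6 iNKT17 against iNKT1 and 6 for B6 iNKT17 against iNKT2. TRBJ counts were 1 for B6 iNKT2 against iNKT1 and 7 for B6 iNKT17 against iNKT1. The TRAV count was 31 for BALB/c CD8T against CD4T.

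With the shared tables kept under both strains, TRBV counts were 0 for iNKT2 between strains, CD4T between strains, CD8T between strains, the strain difference in iNKT2 against iNKT1 and the strain difference in CD8T against CD4T, 1 for BALB/c iNKT2 against iNKT1 and B6 iNKT17 against iNKT1, 2 for B6 iNKT17 against iNKT2, 6 for BALB/c CD8T against CD4T and 8 for B6 CD8T against CD4T. The TRBJ count was 1 for B6 iNKT17 against iNKT2. TRAV counts were 7 for BALB/c CD8T against CD4T and 12 for B6 CD8T against CD4T. Log2 fold changes of the other sign were found for TRBV13-2 (-0.10 in BALB/c iNKT2 against iNKT1), TRBV1 (0.044 in BALB/c iNKT2 against iNKT1, 0.18 in B6 iNKT2 against iNKT1, -0.11 in B6 iNKT17 against iNKT2), TRAV9-3 (0.84 in BALB/c CD8T against CD4T). Differences changed sign in CDR3 length (0.0232 in CD8T against CD4T). Differences passed in log2 inverse Simpson number (-4.68 in iNKT2 against iNKT1, -3.11 in iNKT17 against iNKT1). With them kept as BALB/c, TRBV counts were 0 for iNKT2 between strains and CD4T between strains, 1 for BALB/c iNKT2 against iNKT1 and CD8T between strains and 6 for BALB/c CD8T against CD4T and B6 CD8T against CD4T. TRBJ counts were 1 for BALB/c iNKT2 against iNKT1 and 2 for BALB/c iNKT17 against iNKT1. TRAV counts were 7 for BALB/c CD8T against CD4T and 8 for B6 CD8T against CD4T. The sign turned for TRBV13-2 (-0.10 in BALB/c iNKT2 against iNKT1), TRBV1 (0.044 in BALB/c iNKT2 against iNKT1, 0.0063 in CD4T between strains), TRBV13-1 (0.0075 in iNKT1 between strains), TRAV9-3 (0.84 in BALB/c CD8T against CD4T). A change of sign was seen for differences in CDR3 length (0.0164 in CD8T against CD4T). Calls were gained for log2 inverse Simpson number (-4.30 in iNKT2 against iNKT1, -3.16 in iNKT17 against iNKT1). With them kept as B6, the TRBV count was 1 for B6 iNKT17 against iNKT1. The TRBJ count was 1 for B6 iNKT17 against iNKT2. Signs were the opposite for TRBV1 (0.18 in B6 iNKT2 against iNKT1, -0.11 in B6 iNKT17 against iNKT2, -0.078 in CD8T between strains), TRBV29 (0.10 in iNKT2 between strains). Differences passed in log2 inverse Simpson number (-3.74 in iNKT2 against iNKT1, -2.31 in iNKT17 against iNKT1).

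Within layout B, the TRBV count was 0 for BALB/c iNKT17 against iNKT1. TRBJ counts were 0 for B6 iNKT17 against iNKT2 and 1 for BALB/c iNKT17 against iNKT1. The TRAV count was 33 for BALB/c CD8T against CD4T. In the other direction were TRBV13-2 (-0.055 in BALB/c iNKT2 against iNKT1, 0.052 in B6 iNKT2 against iNKT1), TRBV13-3 (0.21 in BALB/c iNKT17 against iNKT1, 0.024 in BALB/c iNKT17 against iNKT2), TRBV13-1 (0.13 in iNKT2 between strains), TRAV9-2 (0.031 in B6 CD8T against CD4T). A change of sign was seen for differences in CDR3 length (-0.00281 in iNKT against CD4T) and overlap (-0.00121 in B6 same against other number). Calls were lost for log2 clonotype number (-1.15 in iNKT2 against iNKT1, -2.17 in iNKT17 against iNKT1, -1.02 in iNKT17 against iNKT2, -1.42 in iNKT against CD4T), log2 inverse Simpson number (-4.17 in BALB/c against B6), CDR3 length (-0.482 in iNKT2 against iNKT1, 0.502 in iNKT17 against iNKT2), CDR3 length within TRBV13-2 (-0.802 in iNKT2 against iNKT1, 0.814 in iNKT17 against iNKT2) and overlap (0.152 in BALB/c same against other number). With layout as a term of the fit, TRBV counts were 1 for B6 iNKT17 against iNKT1 and B6 iNKT17 against iNKT2 and 12 for the strain difference in CD8T against CD4T. The TRAV count was 33 for BALB/c CD8T against CD4T. Log2 fold changes of the other sign were found for TRBV29 (0.027 in iNKT2 between strains). At 8305 reads per library, calls were lost for log2 clonotype number (-0.42 in iNKT17 against iNKT2). Calls were gained for log2 clonotype number (-0.60 in BALB/c against B6). With B6 iNKT17 2 and 3 numbered 3 and 4, differences passed in overlap (0.0264 in B6 same against other number).

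Over libraries left out in turn, counts of TRBV genes past the threshold ran from 1 (without BALB/c iNKT1 3 or BALB/c iNKT2 4) to 4 in BALB/c iNKT2 against iNKT1, 1 (without BALB/c iNKT1 1 or BALB/c iNKT1 4 or BALB/c iNKT17 1 or BALB/c iNKT17 4) to 4 in BALB/c iNKT17 against iNKT1, 5 (without BALB/c iNKT2 3 or BALB/c iNKT2 4) to 8 in BALB/c iNKT17 against iNKT2, 0 to 1 (without B6 iNKT17 3) in B6 iNKT17 against iNKT2. For TRBJ genes they ran from 2 to 8 (without BALB/c iNKT2 3) in BALB/c iNKT2 against iNKT1, 2 (without BALB/c iNKT17 1) to 4 in BALB/c iNKT17 against iNKT1, 1 to 4 (without BALB/c iNKT2 3) in BALB/c iNKT17 against iNKT2, 0 to 1 (without B6 iNKT2 1 or B6 iNKT2 4) in B6 iNKT2 against iNKT1, 1 (without B6 iNKT2 3 or B6 iNKT17 1 or B6 iNKT17 2 or B6 iNKT17 3) to 2 in B6 iNKT17 against iNKT2. The log2 fold change of TRBV13-2 ran from -0.055 (without BALB/c iNKT2 1) to 0.086 in BALB/c iNKT2 against iNKT1, -0.41 to 0.12 (without B6 iNKT2 4) in B6 iNKT2 against iNKT1, -0.43 to 0.11 (without B6 iNKT2 3) in B6 iNKT17 against iNKT2, -0.42 to 0.11 (without B6 iNKT2 3) in iNKT2 between strains. TRBV13-3 ran from -0.014 (without BALB/c iNKT2 1) to 0.34 in BALB/c iNKT2 against iNKT1, -0.22 to 0.11 (without BALB/c iNKT1 1) in BALB/c iNKT17 against iNKT1. TRBV1 ran from -0.57 to 0.21 (without BALB/c iNKT1 4) in BALB/c iNKT2 against iNKT1, -0.14 (without B6 iNKT17 1) to 0.36 in B6 iNKT17 against iNKT1. TRBV13-1 ran from -0.25 to 0.28 (without B6 iNKT2 3) in B6 iNKT2 against iNKT1, -0.11 to 0.067 (without BALB/c iNKT1 3) in iNKT1 between strains, -0.52 to 0.00090 (without B6 iNKT2 1) in iNKT2 between strains. TRBV29 ran from -0.43 to 0.067 (without BALB/c iNKT1 4) in iNKT1 between strains, -0.15 to 0.17 (without B6 iNKT2 4) in iNKT2 between strains. TRBV16 ran from -0.52 to 0.027 (without BALB/c iNKT1 3) in iNKT1 between strains, -0.41 to 0.042 (without B6 iNKT17 2) in iNKT17 between strains. TRBV15 ran from -0.36 (without BALB/c iNKT1 3) to 1.64 in iNKT1 between strains, -1.40 (without BALB/c iNKT17 3) to 1.59 in iNKT17 between strains. TRAV9-4 ran from -0.10 to 0.013 (without BALB/c CD8T 2) in BALB/c CD8T against CD4T. TRAV4-3 ran from -0.060 to 0.027 (without B6 CD4T 3) in B6 CD8T against CD4T. TRAV9-2 ran from -0.24 to 0.15 (without B6 CD8T 2) in B6 CD8T against CD4T. Log2 clonotype number differences ran from -0.56 (without B6 iNKT17 1) to -0.37 in BALB/c against B6. Log2 inverse Simpson number differences ran from -4.44 (without B6 iNKT2 4) to -1.91 in iNKT2 against iNKT1, -2.84 (without BALB/c iNKT1 4) to -1.95 in iNKT17 against iNKT1, -0.45 (without B6 iNKT2 3) to 2.07 in iNKT17 against iNKT2, -4.77 to -3.08 (without B6 iNKT2 4) in BALB/c against B6. CDR3 length differences ran from -0.576 to -0.326 in iNKT2 against iNKT1, 0.381 to 0.631 in iNKT17 against iNKT2, -0.259 (without B6 iNKT2 3) to -0.0921 in BALB/c against B6. CDR3 length within TRBV13-2 differences ran from -0.866 to -0.376 in iNKT2 against iNKT1, -0.0153 (without BALB/c iNKT1 3) to 0.0844 in iNKT17 against iNKT1, 0.418 to 0.907 in iNKT17 against iNKT2, -0.318 (without B6 iNKT2 3) to 0.00793 (without B6 iNKT2 1) in BALB/c against B6. Overlap differences ran from -0.00231 (without B6 iNKT1 4) to 0.0357 in B6 same against other number.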

Other observations

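Both tests of another numbering of B6 iNKT17 libraries and the summaries of the largest clone were chosen only after the result was seen. TRAV genes other than TRAV11 held 3.24% ± 1.59 of productive TRA reads in BALB/c iNKT libraries (SD, n = 10) and 2.36% ± 1.10 in B6 (n = 9), with 0.938% to 6.60% over all 19. The TRAV1-TRAJ33 alpha chain of MAIT cells held 0.00193% ± 0.00225 in iNKT libraries and 0.0364% ± 0.0220 in CD4T and CD8T libraries (n = 10). TRAV13-TRAJ50 held 0.117% ± 0.184 in BALB/c iNKT libraries (0.00841 to 0.617), 0.00525% ± 0.00426 in B6 iNKT libraries and 0.132% ± 0.0629 in CD4T and CD8T libraries. The highest mean of TRAV13-TRAJ50 among iNKT groups was in BALB/c iNKT1, at 0.282% ± 0.292 (n = 3), and 0.115% without BALB/c iNKT1 3. TRD and TRG clones averaged 3.42 reads per iNKT library and 22.2 per CD4T or CD8T library. They followed the layout, with means of 8.43 (7 libraries) in layout A and 0.5 (12) in layout B for iNKT, and 73.5 (2) and 9.38 (8) for CD4T and CD8T.

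The largest TRB clone held 4.59% ± 3.00 of productive TRB reads in BALB/c iNKT libraries (SD, n = 10) and 4.41% ± 10.4 in B6 iNKT libraries (n = 9). The B6 values were 0.176% ± 0.0459 in iNKT1, 11.4% ± 17.9 in iNKT2, where B6 iNKT2 3 held 31.9%, and 1.70% ± 1.60 in iNKT17 (n = 3 each).

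In B6, same-number pairs of iNKT libraries overlapped by 0.0171 more than other-number pairs (exact one-sided permutation p 0.222), and by -0.00121 within layout B. A hypothesis found in these values is that B6 iNKT17 libraries 2 and 3 may come from the animals or pools numbered 3 and 4 in the other subsets. Numbered that way, same-number pairs averaged 0.0530 (9 pairs) against 0.0266 (18 pairs), a difference of 0.0264, with an exact one-sided permutation p of 0.0278 over 36 regroupings. That numbering also brings libraries of the same layout together, so pairs of iNKT17 with iNKT1 or iNKT2 were compared within layout B. There the mean of same-number pairs exceeded that of other-number pairs by 0.0238, and all 4 same-number pairs (0.0292 to 0.0574) lay above all 4 others (0.000309 to 0.0255). The hypothesis goes with both tests and stays a hypothesis, as it was drawn from the same values and the labels give no animal.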
